A study of Phaseolus vulgaris with 2 samples.

How the data were processed

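Nuclei from root tips of common bean (Phaseolus vulgaris) were profiled in 2 single-nucleus RNA-seq libraries of 1 group, both labelled as mock samples of the genotype L88-57. What mock stands for is not said in the labels. Per the labels' protocols, seedlings grew on agar with B&D medium, roots of plants aged 6 days were chopped, and nuclei passed filters of 30 and 40 µm. Libraries were made with a droplet kit that reads the 3' end of transcripts and were sequenced on an Illumina platform. The labels number the libraries replicate 1 and replicate 2. They do not say that these came from separate plants or nuclei preparations. The p-values of the gene tests below thus measure only how far differences between clusters vary between these 2 libraries. That spread may be technical.

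The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, per the file headers and the whole-number values. The matrix headers name cellranger 7.0.0, while the submitters' processing notes name Cell Ranger 4.1.1, and which version made the counts could not be settled. The genome build and whether intronic reads were counted are not given in the sources used here. The lowest UMI total of a barcode was 500 in both libraries, so droplets below that total were not analysed here and the level of free RNA in empty droplets was not measured.

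The feature tables list 27433 gene IDs and repeat the ID in place of a gene name. Of these, 0 matched the 34165 genes of the RefSeq table at hand, whose assembly is P. vulgaris v2.0 and which holds a locus tag for 181 genes. Gene names, products and coordinates were therefore not used. The cell type markers, gene lists and protein motifs fixed before the data were examined could not be looked up, clusters are given by number, and no list test (camera or fry) was run. IDs are printed as deposited. Gene order along the 11 chromosomes was read from the numbers in the IDs of 27012 genes, a naming convention that the files do not test.

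Barcodes with at least 500 UMIs, at least 300 genes and at most the 99.5th percentile of UMIs of their library were kept. This left 2638 of 2653 in replicate 1 and 5350 of 5377 in replicate 2. Scrublet at its own threshold called 2 doublets in replicate 1 (0.0758%) and 0 in replicate 2. For replicate 2 the fallback fixed in advance applied (under 0.5% called among over 5000 nuclei), and the 229 highest scores (4.28%) were removed. The libraries were thus cleaned by different rules. The 7757 nuclei used comprise 2636 from replicate 1 and 5121 from replicate 2.

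Each UMI was assigned at random to clustering (70%) or to testing (30%), so that genes were tested on UMIs that took no part in making the clusters. Clusters were made in Seurat 5.3.0 (R 4.3.3) from 18777 genes seen in at least 10 nuclei: log-normalization, 2000 variable genes, 30 principal components, canonical correlation integration of the libraries, and Louvain clustering at resolution 0.5 with seed 1. The number of Louvain starts was not fixed in advance. With Seurat's default of 10 starts, clusterings made with different kernels of the linear algebra library, which differ only in rounding, reached an adjusted Rand index of 0.861. With 100 starts and 50 iterations it was 0.948. The larger number was adopted for that reason, after gene tests on default-start clusterings had been seen and before any on the clustering used here. The default is among the alternatives.

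Testing UMIs were summed per cluster and library and fitted with edgeR 4.0.16 (TMM, filterByExpr by cluster, quasi-likelihood F-test), with the library as a block. Each cluster was compared with the mean of the other tested clusters on the log scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes and clusters and a log2 fold change of at least 1 in size. Clusters with under 20 nuclei in either library were left out. The fit had 18 residual degrees of freedom, all from repeated clusters of the same 2 libraries, and a biological coefficient of variation of 13.4%. Testing UMIs per cluster and library ran from 14370 to 419941. Fitted log2 fold changes of genes with few UMIs in the other clusters depend on the prior count, so CPM values and their ratios are printed first. SEs printed for edgeR are the size of the log2 fold change divided by the square root of its F statistic.

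The rule fixed for named genes took, per cluster, the largest log2 fold changes among genes called higher, with at least 50 CPM in the cluster in each library and higher in both, and with an informative product name. The product clause could not be applied, and 2 genes per cluster are given in place of 4 because the IDs carry no names. The 2 lower genes were chosen after their values were seen: the largest lower bounds of the fold among calls with 0 testing UMIs in the cluster, against a floor of 3 UMIs over both libraries. Library pairs were compared by Pearson and Spearman correlation of log2(CPM + 1) across genes. Shares carry Wilson 95% intervals, which cover counting error only. Depth was compared after thinning each nucleus to 1000 UMIs, leaving out 513 and 1485 shallower nuclei of replicates 1 and 2.

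Counts were simulated from the pooled profile of all tested clusters at the depth of each cluster and library, with 1 fixed dispersion. A seeded set of genes was changed in 1 cluster, and the test was tried on these counts. In cluster 3, where the shallower library was deepest, over 6230 tested genes it recovered 40.3% of 2-fold, 98.5% of 4-fold and 100% of 8-fold changes. In cluster 16, where it was shallowest, over 6190 tested genes the shares were 11.9%, 86.6% and 100%. No unchanged gene was called in the altered cluster, and 5 and 6 were called across the other clusters. The simulated counts held no other differences between clusters or libraries, so these rates may not carry over to the real clusters. A simulation of 813 nuclei of 1 kind gave 0 calls both with and without the UMI split, so it does not show what the split changes.

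Alternatives comprised RLE size factors, DESeq2 1.42.0, no low-count filter, no library block, no minimum fold, no UMI split, a second split, resolutions 0.3 and 1.0, no integration, doublets kept, and nuclei with at least 1000 UMIs. Added after the data were seen were 10 Louvain starts, another linear algebra kernel, top doublet scores removed in both libraries, and every cluster thinned to equal depth, the last also for the correlation between clusters (mean of 20 draws). Python 3.11.15 and scipy 1.17.1 were used for the remaining steps.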

Results

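The series is an atlas of the common bean root, built from nuclei of root tips of seedlings aged 6 days. It holds 1 group with 2 libraries, so the comparisons its design implies are between kinds of nuclei, each seen in both libraries. Replicate 1 held 2653 nuclei with 9287093 UMIs and a median of 2025 UMIs and 1351 genes per nucleus. Replicate 2 held 5377 nuclei with 10332595 UMIs and medians of 1433 UMIs and 1040 genes. UMIs were seen for 21106 and 20899 genes. Once each nucleus was thinned to 1000 UMIs, the median was 780 genes in replicate 1 and 782 in replicate 2.

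The 7757 nuclei used fell into 20 clusters, which are given by number because the gene IDs could not be paired with names or cell type markers. Cluster 1 held 1108 nuclei, 11.04% of replicate 1 (Wilson 95% interval 9.90 to 12.3%) and 15.95% of replicate 2 (14.98 to 16.98%), a mean of 13.5% ± 3.48 (SD, n = 2). Cluster 2 held 1082 nuclei at 13.7% (12.4 to 15.1%) and 14.1% (13.2 to 15.1%), a mean of 13.9% ± 0.272 (SD, n = 2). Of the 19 clusters with at least 20 nuclei in both libraries, 16 had shares within 1.5-fold of each other. Intervals of the libraries overlapped in 13 of the 20 clusters and did not in 7. The largest ratio between the shares of a tested cluster was in cluster 16, with 136 nuclei or 5.16% of replicate 1 (4.38 to 6.07%) against 21 nuclei or 0.410% of replicate 2 (0.268 to 0.626%), a mean of 2.78% ± 3.36 (SD, n = 2). Cluster 20 held 24 nuclei of replicate 1 (0.910%, 0.613 to 1.35%) and 10 of replicate 2 (0.195%, 0.106 to 0.359%), a mean of 0.553% ± 0.506 (SD, n = 2), and was left out of the tests.

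**Figure D1:**
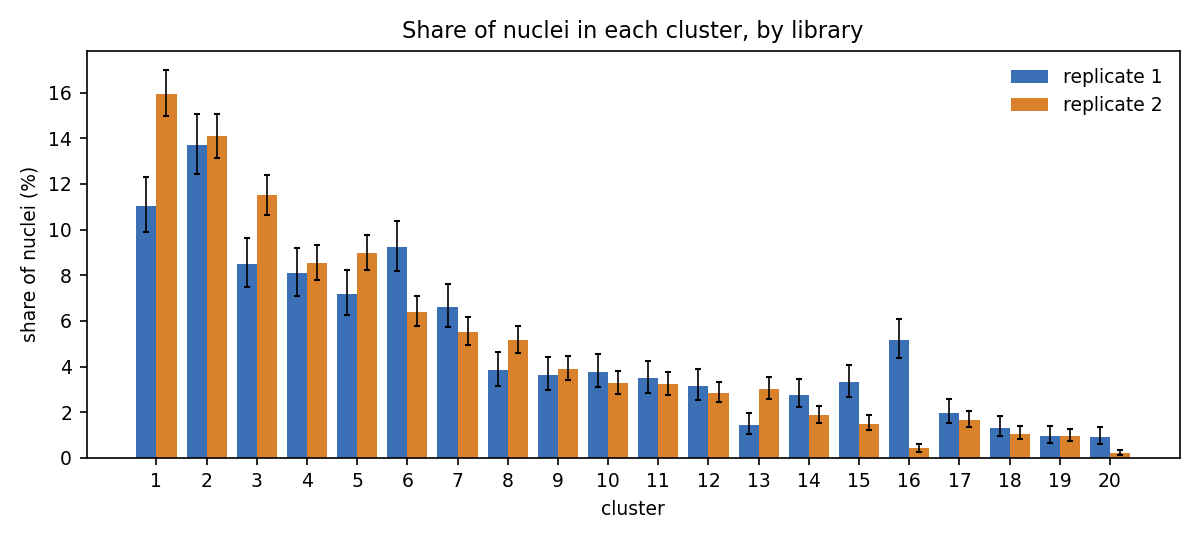
Share of nuclei (%) in each of the 20 clusters, blue for replicate 1 and orange for replicate 2; bars are the share in 1 library and error bars its Wilson 95% interval, which covers counting error only. Cluster 16 holds 5.16% of replicate 1 and 0.410% of replicate 2.

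Which genes set each kind of nucleus apart was asked by comparing every tested cluster with the mean of the other 18. Most tested genes, 5795 of 8233 (70.4%), were higher in at least 1 cluster, and 1915 of these (33.05%) in exactly 1. Calls added up to 13534 higher and 2235 lower, the lower ones from 1530 genes. Both libraries went the same way in 13096 (96.8%) of the higher calls, and the share was lowest in cluster 16, at 82.7%. The calls come from a fit to the same 2 libraries, so this agreement is partly built in. Genes called higher per cluster ran from 317 in cluster 18 to 1062 in cluster 5. The total depends on depth: with every cluster and library thinned to 14370 UMIs, an alternative added after the data were seen, 1131 higher and 84 lower calls were made, and cluster 13 led with 107. Genes called here describe the clusters and are no difference between conditions.

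**Figure D2:**
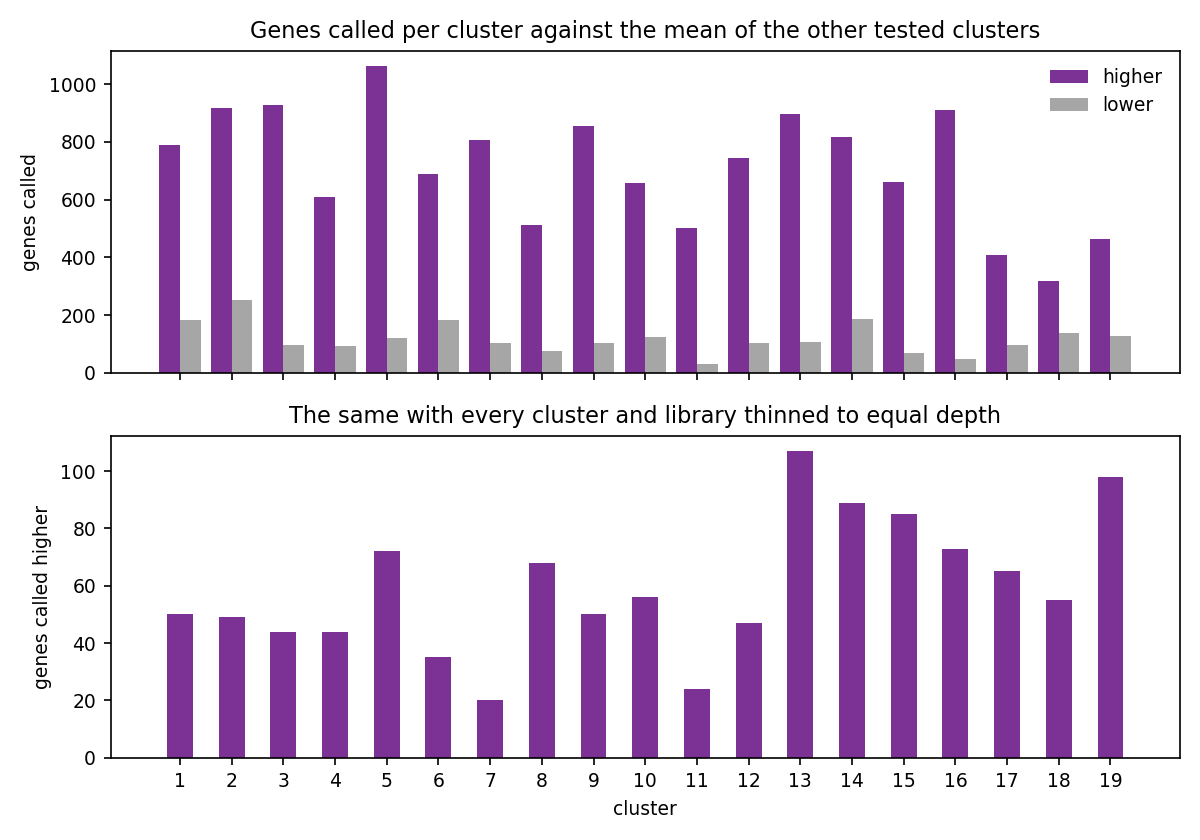
Genes called per tested cluster against the mean of the other tested clusters (top, purple higher and grey lower) and genes called higher after each cluster and library was thinned to 14370 UMIs (bottom); both vertical axes count genes. Cluster 5 has the most higher calls before thinning (1062) and cluster 13 after it (107).

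In what follows, values are means ± SD over the 2 libraries (n = 2) in CPM of the testing UMIs, in the cluster and over the other tested clusters, with the ratio of the means. All 38 genes named as higher passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p from 1.14e-133 to 4.38e-11. Being higher in both libraries was part of the naming rule. Their fitted log2 fold changes ran from 3.63 to 9.45. Of the 38, 11 were called higher in exactly 1 cluster, 15 in 2 clusters and 12 in 3 or more. A gene called higher in several clusters need not be highest in the one it is named for. For 17 of them the cluster's mean was at least 100 times that of the others.

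In cluster 19, with 75 nuclei and 462 genes called higher, Phvul.005G122200.v2.1 reached 2839 ± 1156 CPM against 6.67 ± 3.20, 426-fold (log2 fold change 9.45 ± 0.36 SE). Phvul.001G003800.v2.1 stood at 2039 ± 327 CPM there against 8.65 ± 4.99, 236-fold. Cluster 17 had the highest level of any gene named, Phvul.010G034132.v2.1 at 5505 ± 899.9 CPM against 19.4 ± 12.6 (284-fold). Its second gene, Phvul.003G010600.v2.1, had 1957 ± 179 CPM against 6.61 ± 2.14 (296-fold), and 409 genes were called higher. Cluster 18 (317 genes) was led by Phvul.007G199000.v2.1 at 883 ± 276 CPM against 5.49 ± 2.62, 161-fold, and by Phvul.002G333500.v2.1 at 523 ± 125 CPM against 4.73 ± 1.40, 111-fold. Both of its genes were higher in this cluster alone.

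In cluster 15, with 660 genes called higher, Phvul.010G088400.v2.1 had 1389 ± 473 CPM against 2.68 ± 1.27, 518-fold. Such ratios rest on few UMIs in the other clusters and differ between the libraries, here 1055 CPM against 3.58 in replicate 1 and 1724 CPM against 1.78 in replicate 2. Phvul.003G035100.v2.1 had 2091 ± 289 CPM there against 5.46 ± 2.67, 383-fold, and neither gene was called higher in another cluster. Cluster 16 (910 genes) was led by Phvul.007G231100.v2.1 at 479.7 ± 317 CPM against 11.8 ± 7.01 (40.8-fold) and Phvul.010G012900.v2.1 at 129 ± 29.4 CPM against 3.65 ± 3.25 (35.3-fold). The values of cluster 16 in replicate 2 rest on 21 nuclei and 14370 testing UMIs. By DESeq2's Wald test with Benjamini-Hochberg adjustment the calls of Phvul.010G088400.v2.1 (adjusted p = 0.529) and Phvul.010G012900.v2.1 (0.480) did not pass. Their log2 fold changes were 9.12 ± 0.393 and 5.55 ± 0.748 (SE) in edgeR and 8.45 ± 6.47 and 5.54 ± 3.91 in DESeq2. In all 10 named genes that lost the call with DESeq2 the fold stayed within 0.767 log2 units of edgeR's. The SE of DESeq2's Wald test was 3.09 to 16.5 times the one derived from edgeR's F statistic. These 2 kinds of SE are not computed alike.

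By the mean over both libraries, the cluster nearest to cluster 13 was cluster 14 (r across genes 0.637). In cluster 13, with 896 genes called higher, Phvul.009G071900.v2.1 had 1317 ± 208 CPM against 8.735 ± 2.35 (151-fold), and Phvul.002G319104.v2.1 had 1005 ± 311 CPM against 3.31 ± 0.784 (304-fold). Nuclei of cluster 13 were deep in replicate 1, with a median of 4449 UMIs, and not in replicate 2, with 1376. Cluster 14 (817 genes) was led by Phvul.003G006100.v2.1 at 461 ± 26.9 CPM against 3.23 ± 1.98, 143-fold, and Phvul.004G068200.v2.1 at 333 ± 216 CPM against 5.23 ± 2.26, 63.6-fold. Neither gene of cluster 14 passed DESeq2's Wald test, with adjusted p of 0.609 and 0.186. Phvul.003G151200.v2.1 was lower in cluster 14: 0 of 162843 testing UMIs, against 326 ± 54.9 CPM in the others, at least 17.7-fold lower against a floor of 3 UMIs over both libraries (edgeR's quasi-likelihood test, adjusted p = 0.00749). Over all UMIs of these nuclei it had 1 of 541614. The gene was called higher in 6 other clusters, which raise the mean of the others. On the log2 scale with a prior count of 2, its difference from the mean of the other clusters was -2.08 in replicate 1 and -2.49 in replicate 2. The lower call ended with the second split of UMIs, in nuclei of at least 1000 UMIs, with 10 Louvain starts and at equal depth. Of these, the second split had the lowest adjusted p by edgeR's quasi-likelihood test (0.0642). The fitted log2 fold change of -5.67 was -5.38, -5.37, -5.44 and -2.24 in these settings in turn, and -3.97 without the split, where the call stood.

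Clusters 9, 10 and 12 each had a gene above 1000 CPM with a mean under 20 CPM over the other clusters. Phvul.008G129900.v2.1 had 1990.35 ± 245 CPM in cluster 9 against 7.69 ± 0.450, 259-fold, and was higher in no other cluster. Phvul.005G177000.v2.1 had 2796 ± 874 CPM there against 13.3 ± 8.34, 210.1-fold. Its fitted log2 fold change of 8.43 was 2.80 with 10 Louvain starts and 1.36 without the split of UMIs, where the call ended (edgeR adjusted p = 0.339). In cluster 10 the genes were Phvul.004G166650.v2.1, 1164 ± 58.2 CPM against 3.48 ± 3.76 (335-fold), and Phvul.001G021700.v2.1, 692 ± 175 CPM against 1.61 ± 1.20 (431-fold). In cluster 12 they were Phvul.006G061800.v2.1, 2001 ± 49.2 CPM against 10.2 ± 5.50 (197-fold), and Phvul.010G064300.v2.1, 818 ± 13.9 CPM against 7.06 ± 4.56 (116-fold). Under DESeq2 both genes of cluster 10 (adjusted p 0.0956 and 0.572) and Phvul.010G064300.v2.1 (adjusted p 0.110) lost the call. Genes called higher numbered 853, 657 and 744 in clusters 9, 10 and 12.

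Clusters 1 and 3 were the closest pair, with a mean r of 0.865, and formed 1 cluster at resolution 0.3. Phvul.007G257300.v2.1 had 333 ± 132 CPM in cluster 1 against 41.9 ± 28.4 (7.94-fold), and Phvul.006G022200.v2.1 had 156 ± 128 CPM against 28.9 ± 2.84 (5.41-fold). In cluster 3 Phvul.002G318100.v2.1 had 131 ± 2.09 CPM against 6.19 ± 2.59 (21.1-fold), and Phvul.002G039300.v2.1 had 144 ± 40.0 CPM against 6.70 ± 1.51 (21.5-fold), the latter not passing DESeq2 (adjusted p = 0.0548). In cluster 2 Phvul.007G222900.v2.1 had 193 ± 26.4 CPM against 5.21 ± 0.826 (37.1-fold) and Phvul.003G003100.v2.1 had 251 ± 145.2 CPM against 15.2 ± 16.7 (16.6-fold). Genes called higher numbered 789, 916 and 926 in clusters 1, 2 and 3. Directly between clusters 1 and 3, 140 genes were higher in cluster 1 and 413 in cluster 3.

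Clusters 4 and 6 were each other's nearest by the mean over both libraries (r = 0.761) and also formed 1 cluster at the lower resolution. Phvul.009G123700.v2.1 had 290.0 ± 13.98 CPM in cluster 4 against 4.34 ± 0.192, 66.9-fold, and Phvul.002G244900.v2.1 had 743 ± 94.7 CPM against 12.7 ± 0.925, 58.4-fold. The fitted log2 fold change of Phvul.009G123700.v2.1, 6.75, was 4.92 in the second split of UMIs, 4.84 with 10 Louvain starts, 5.18 without integration and 4.74 without the UMI split, and that of Phvul.002G244900.v2.1, 6.52, rose to between 8.31 and 8.43 in the last 3 of these settings. In cluster 6 Phvul.011G117600.v2.1 had 174 ± 73.0 CPM against 10.7 ± 4.74, 16.2-fold, and Phvul.002G250600.v2.1 had 127 ± 6.52 CPM against 10.9 ± 0.537, 11.7-fold. Directly between them, 217 genes were higher in cluster 4 and 164 in cluster 6. Phvul.006G207800.v2.1 was lower in cluster 6, with 0 of 255409 testing UMIs against 137 ± 54.1 CPM (edgeR's quasi-likelihood test, adjusted p = 0.00411). Over all UMIs of these nuclei it had 10 of 851315, and whether those came from free RNA was not tested. The gene was called higher in 4 other clusters, which raise the mean of the others. On the log2 scale with a prior count of 2, its difference from the mean of the other clusters was -1.84 in replicate 1 and -1.86 in replicate 2. How much lower it was depends on the processing, since the fitted log2 fold change of -5.25 was -1.06 without the UMI split (adjusted p = 0.0856), -2.55 without integration (adjusted p = 1.00) and -2.20 with top doublet scores removed in both libraries (adjusted p = 0.0625), where the call ended. Cluster 4 had 609 genes called higher, and this count fell to 382 without integration and 333 with 10 Louvain starts.

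Clusters 5 and 7 formed 1 cluster at resolution 0.3, and so did clusters 8 and 19. In cluster 5 Phvul.006G077200.v2.1 had 282 ± 17.97 CPM against 7.98 ± 2.38 (35.4-fold) and Phvul.009G189000.v2.1 had 438 ± 83.1 CPM against 18.5 ± 12.04 (23.7-fold). Cluster 7 (805 genes) was led by Phvul.007G011100.v2.1, 219 ± 51.8 CPM against 5.25 ± 2.35 (41.8-fold), and Phvul.007G012700.v2.1, 169 ± 37.6 CPM against 11.96 ± 3.63 (14.1-fold). In cluster 8 (511 genes) Phvul.003G148200.v2.1 had 291 ± 37.2 CPM against 52.3 ± 11.1 (5.57-fold) and Phvul.003G045200.v2.1 had 220.5 ± 111 CPM against 39.8 ± 15.3 (5.53-fold). Both were higher in 3 clusters, which raises the mean of the others, and cluster 8 need not be their highest. They had 45 and 31 testing UMIs in cluster 8, and 72 and 53 in the other clusters. Cluster 11 (503 genes) was led by Phvul.005G066100.v2.1, 189 ± 44.2 CPM against 6.89 ± 2.099 (27.4-fold), and Phvul.001G030100.v2.1, 461 ± 42.6 CPM against 25.2 ± 4.37 (18.3-fold). DESeq2 ended the calls of Phvul.007G011100.v2.1 (adjusted p = 0.0515) and Phvul.003G045200.v2.1 (adjusted p = 0.636). Without the UMI split the log2 fold change of Phvul.007G011100.v2.1 was 3.31, from 6.07, and that of Phvul.003G148200.v2.1 was 4.46, from 6.12; the latter was 4.11 with doublets kept.

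How far the clusters were alike was described by the correlation of log2(CPM + 1) across genes, which are not independent replicates. Clusters 16 and 19 were the farthest apart of the tested pairs, with a mean r of 0.277. The libraries did not agree on every r: that of cluster 16 with cluster 11, its nearest, was 0.717 in replicate 1 and 0.342 in replicate 2, where cluster 16 had 21 nuclei. With every cluster and library thinned to 14370 UMIs, an alternative added after the data were seen, these were 0.2999 and 0.2270, clusters 1 and 3 were still the closest pair (mean r of 0.406) and clusters 16 and 19 the farthest (0.181), and the nearest cluster stayed the same for 14 of the 19. Without thinning, each cluster had between 140 and 657 genes higher than its own nearest cluster. Also without thinning, the nearest cluster was the same in both libraries for 12 of the 19. With gene means removed, 18 of the 19 clusters matched themselves best between the libraries in both directions. The exception was cluster 11, where replicate 1 matched cluster 7 of replicate 2 (r = 0.269) about as well as its own counterpart (r = 0.263). Clusters were made from both libraries together after integration, so such matches are partly built in.

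**Figure D3:**
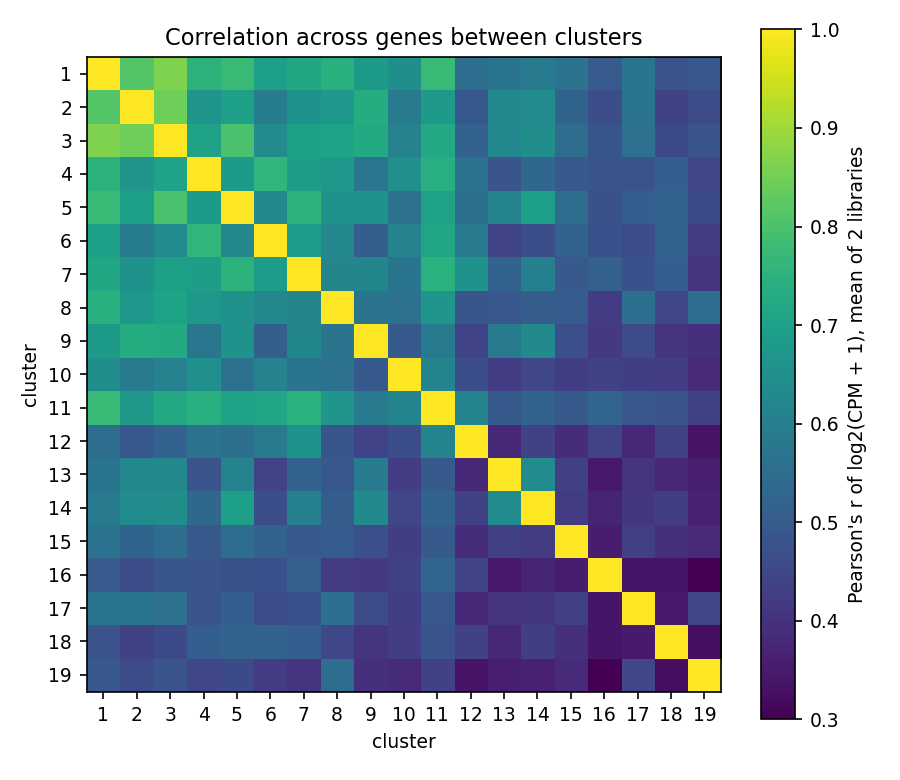
Pearson's r across genes of log2(CPM + 1) between tested clusters, averaged over the 2 libraries; both axes list the 19 clusters by number, and the colour scale runs from 0.3 (dark) to 1.0 (yellow). Clusters 1 and 3 are the closest pair (0.865) and clusters 16 and 19 the farthest (0.277, below the end of the scale). The r also depends on depth; thinned to 14370 UMIs per cluster and library, these pairs have 0.406 and 0.181.

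Summed over all nuclei, the libraries had a Pearson r of 0.971 and a Spearman rho of 0.972 across 21452 genes. Within the tested clusters the Pearson r ran from 0.932 in cluster 5, with 960732 and 1157210 UMIs, to 0.422 in cluster 18, with 89916 and 92258. The low end depends on how genes with few UMIs are treated: cluster 18 had 0.669 with a pseudocount of 10 and 0.773 over genes with at least 10 UMIs in both libraries, where cluster 16 was lowest (0.570, over 887 genes). Of 5880 genes at 50 CPM or more in either library, 246 (4.18%) were over 2-fold apart and 27 over 4-fold, 21 of them higher in replicate 1 and 6 in replicate 2. The gene farthest apart in each direction is given, chosen after the values were seen. Phvul.010G066400.v2.1 had 141 CPM in replicate 1 and 0.440 CPM (4 UMIs) in replicate 2, and was higher in replicate 1 in all 19 tested clusters. Cluster 16 held most of its level: without that cluster it had 25.7 CPM in replicate 1 and 0.442 CPM in replicate 2, and the log2 ratio fell from 6.62 to 4.21. Phvul.011G125200.v2.1 had 335 UMIs (38.2 CPM) in replicate 1 and 2221 UMIs (244 CPM) in replicate 2, again in the same direction in all 19. With 1 library on each side no test of these differences was possible.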

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

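Doublets kept, a minimum of 1000 UMIs and no integration were planned settings; their use as tests of cluster 16, and the other tests in this part, were chosen after the results were seen. The bounds for free RNA were rewritten after a first result. Cluster 20 drew attention as a signal in nuclei that no comparison used, since it was left out of the tests for having 10 nuclei in replicate 2. Among genes with at least 10 testing UMIs there in replicate 1, 107 stood at least 8-fold above the mean of the tested clusters. Of these, 88 were also at least 2-fold above it in replicate 2. Cluster 20 had 4559 testing UMIs in replicate 2, so 1 UMI of a gene could pass that mark. The 88 thus show little more than that a UMI was seen, and no share for other genes was computed. Phvul.011G139300.v2.1 had 80 UMIs in replicate 1, or 3732 CPM (exact Poisson 95% interval 2959 to 4645) against 0.506 CPM on average in the tested clusters. In replicate 2 it had 4 UMIs, or 877 CPM (239 to 2246) against 0.277 CPM. The gene next in rank, Phvul.005G092700.v2.1, also had 80 UMIs in replicate 1, against 0.775 CPM in the tested clusters, and 0 UMIs in replicate 2 (0 to 809 CPM, against 0.732 CPM), so its level did not repeat. These intervals cover counting error only, and no test was made.

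The share of cluster 16 was 12.6 times as high in replicate 1 as in replicate 2 (counting interval 7.97 to 19.9). Unequal removal of doublets is argued against, since the ratio was 13.4 with doublets kept. Shallow nuclei are argued against by a ratio of 12.97 among nuclei with at least 1000 UMIs. Without integration the ratio was 17.4, which does not settle whether the integration misplaced nuclei. Clusters made without it took the number of the integrated cluster that held most of their nuclei. They could also part by library, which would raise the ratio. Whether the preparations differed in tissue or plants cannot be told apart from other differences between these 2 libraries, with 1 library on each side. The design names no biological difference between the libraries, so no biological explanation was tested.

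Genes of cluster 16 were also higher in replicate 1 outside it. In replicate 1 alone, 93 genes were chosen at 200 CPM or more and at least 8-fold higher inside the cluster than outside. Over the other nuclei their median log2 ratio of replicate 1 to replicate 2 was 0.86. Sets of genes matched on level had 0.05 (middle 95% from -0.02 to 0.14). These sets were not chosen in replicate 1, so a part of the difference may come from the choice. Of the 93, 78 were not over 4-fold higher in replicate 1 over all nuclei, and their median was 0.826 (quartiles 0.685 to 0.991). Whether free RNA from cluster 16 nuclei is a part of the cause cannot be told. The median exceeded the matched sets in 17 of the 18 other tested clusters, where all 18 were set as the mark. With 10 Louvain starts it was 17 of 18, and with another linear algebra kernel 16 of 18. Any difference between the libraries that raised these genes throughout replicate 1 could give such counts. In the clustering used, cluster 18 exceeded the matched sets only marginally. The exception, cluster 17, rests on 293 and 250 UMIs with a ratio of 1.02 (0.789 to 1.32). By summed CPM the excess was uneven, with a ratio of 1.23 (1.09 to 1.38) in cluster 10 and 4.07 (3.44 to 4.82) in cluster 13. Intervals of such ratios treat UMIs as independent counts and leave out the spread between nuclei. With nuclei drawn with replacement, the excess in cluster 10 was 2.96 UMIs per nucleus (-8.53 to 14.3). One pool of free RNA should add alike to all clusters, but in replicate 1 the excess over the level of replicate 2 ran from 0.116 UMIs per nucleus in cluster 17 (-2.64 to 2.86, from nuclei drawn with replacement and adjusted for 18 clusters) to 25.8 in cluster 13 (5.26 to 61.3). Whether free RNA is the whole cause cannot be told: the highest lower bound was 2.47 times the lowest upper bound per nucleus but 1.37 times in CPM, under the 2 that was set as the limit on both scales, since nuclei of 1 cluster vary widely. Whole nuclei of cluster 16 placed in other clusters stay open too; a test of this on genes chosen for the difference itself was dropped. Droplets without nuclei, which would separate these explanations, were not analysed here.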

How the results depend on the processing

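Of the alternatives, 10 Louvain starts, another linear algebra kernel, top doublet scores removed in both libraries and equal depth (also for r between clusters) were added after the data were seen; the others were planned. Where a value moved, the cause was not tested unless it is stated. The 13534 higher calls ranged from 9712 (resolution 0.3, which merges clusters) to 16024 (no minimum fold change) in the settings that kept the total within 1.5 times. Without the filter on low counts, which tests more genes, there were 21231, with 1542, 1784, 1846, 1016, 2014, 1070, 1438, 1082 and 1547 in clusters 1 to 7, 10 and 16. Without the split of UMIs, which gives the test more UMIs and reuses those of the clustering, there were 22601 higher and 6336 lower calls. The higher ones were 1598, 1195 and 1444 in clusters 5 to 7, then 1300, 1215, 1004, 1582, 1528, 1519, 1149, 1713, 802, 759 and 960 in clusters 9 to 19. At equal depth, with fewer UMIs by construction, 1131 higher and 84 lower calls were made. In clusters 1 to 19 in order the higher calls were then 50, 49, 44, 44, 72, 35, 20, 68, 50, 56, 24, 47, 107, 89, 85, 73, 65, 55 and 98. Cluster 1 had 512 with DESeq2 and 1184 with no minimum fold change. Cluster 4 had 382 without integration and 333 with 10 Louvain starts. No replicate block gave 1281 lower calls, against 2235, and changed no count of higher calls by over 1.5 times. No count was made for cluster 16 without integration, with at least 1000 UMIs or with another kernel, where it had under 20 nuclei in replicate 2, nor for clusters 6 and 18 in the second split, clusters 3, 6, 7 and 19 at resolution 0.3 and cluster 19 at resolution 1.0, where other clusters took their nuclei. The mean share of cluster 1 was 24.6% at resolution 0.3. That of cluster 2 was 13.3% without the split, 13.3% at resolution 0.3, 13.1% at resolution 1.0, 14.2% without integration and 11.6% in nuclei of at least 1000 UMIs. Leaving out a library gave shares of 11.04 to 15.95% for cluster 1, 13.7 to 14.1% for cluster 2, 0.410 to 5.16% for cluster 16 and 0.195 to 0.910% for cluster 20. With 2 libraries these lie within 1 SD of the mean by construction. The Pearson r of the libraries was 0.974 with a pseudocount of 10 and 0.961 over genes with at least 10 UMIs in both. At equal depth the mean r of clusters 1 and 3 was 0.406 and that of clusters 16 and 19 was 0.181, lower by construction. Thinning to 500 UMIs gave medians of 423 and 424 genes, lower by construction. Of 40 named genes, 0 reversed and 27 passed in every alternative that gave a value. Of the other 13, 10 lost the call with DESeq2, and Phvul.005G177000.v2.1, Phvul.003G151200.v2.1 and Phvul.006G207800.v2.1 lost it in other settings. The fitted log2 fold change of 5 of the 38 higher genes and of both lower ones moved by over 1.5 in at least 1 setting, equal depth and single libraries aside. At equal depth 14 of the 40 genes still gave a value. Values from 1 library alone are log2 ratios with a prior count of 2 and no test, and their direction was fixed by how the 40 genes were chosen. The planned list tests were not run, as no gene ID matched a name. Depth limits the calls: 203 of the lower calls had 0 testing UMIs in their cluster. In simulation 2-fold changes were mostly missed, but they lie at the minimum fold change of a call, so that miss does not measure depth alone.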

Other observations

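All tests in this part were chosen after the result was seen. Genes next to each other by ID were called higher in the same cluster more often than chance. Counting gene and cluster pairs, 719 adjacent pairs were called together, where shuffling the tested genes over their places gave 414 ± 22.2 (SD over 2000 shuffles), a ratio of 1.74 (one-sided permutation p = 0.0005, the smallest these shuffles can give). By the same permutation test the ratio was 1.15 at a distance of 2 genes (p = 0.005), 1.11 at 3 (p = 0.0255), 1.03 at 5 (p = 0.328), 1.18 at 10 (p = 0.001), 1.00 at 20 (p = 0.486) and 1.10 at 50 (p = 0.039), none adjusted for the number of distances tried. Runs of at least 3 consecutive genes called higher in 1 cluster numbered 40, and the longest held 4 genes, no longer than the longest run of 5 in shuffled orders. In 1 of the runs of 4, in cluster 8, the genes had log2 fold changes from 1.98 to 3.44.

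Reads counted at the next gene, or shared by adjacent copies of a gene, could give such adjacent pairs. Acting on adjacent genes only, they would not raise pairs 2 to 5 genes apart with no called gene between them. Copies parted by an uncalled gene could still share reads, so a raised count would not exclude shared reads. Such separated pairs numbered 1465, or 1.02 times the shuffled mean of 1443 (permutation p = 0.288). The ratio was 1.07 with 10 Louvain starts (permutation p = 0.011) and 1.05 with another linear algebra kernel (permutation p = 0.0635), so the answer depends on the clustering and the explanation stays open. Adjacent pairs themselves were 1.80 times the shuffled mean in both of those clusterings. With more adjacent calls than in shuffled orders, more of the observed separated pairs may have been dropped for a called gene between. The ratio for separated pairs may thus be too low, and a value near 1 need not mean no excess. Alignments and gene coordinates, which would separate copies from neighbours, were not used here.

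Of the 21 genes over 4-fold higher in replicate 1, 15 were at least 8-fold higher inside cluster 16 than outside it in that library. Without cluster 16, 12 of the 21 were still over 4-fold apart, and the median log2 ratio of the 21 went from 2.67 to 2.09. All 6 genes higher in replicate 2 stayed over 4-fold apart. Of the 27 genes, 11 differed in the same direction in every tested cluster.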
